A study of Mus musculus with 8 samples.

How the data were processed

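The series holds 8 expression arrays of medulloblastomas from 15-day-old mice, 4 with Cre-conditional deletion of Bcl2l1 and 4 controls. Total RNA was labelled with an Affymetrix whole-transcript kit, per the labels' protocols. The deposited values are on a log2 scale, and per the labels they are RMA expression values from the gene expression workflow of the Partek software. RMA corrects background, normalizes arrays and summarises probes into probe sets, and it compresses differences near background. The version of Partek and the options of the workflow are not given in the sources used here, no genome build is named, and scanner files were not used here. The values lie between 0.68 and 13.2. Array medians differ slightly, so the deposited probe sets were not quantile-normalized to exactly equal distributions.

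Groups were taken from the sample titles, which match the genotype field. A second field on Bcl2l1 status reads deleted for all 8 samples, the controls included, so it was not used. The design text speaks of separate replicate animals, and no batch, litter or scan date is given. Replicate numbers are shared between the groups without a stated pairing.

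Of 41345 probe sets, the platform annotation gave 23521 a single gene symbol, 1814 several symbols and 16010 none. Symbols were updated through Entrez identifiers with a RefSeq gene table of another stated source (assembly GRCm38.p6), which matched 23328 and left 193, and changed 0 symbols. That table served only for names and for the order of neighbouring genes, and no coordinates were taken from it. Where several probe sets named a gene, as for 1082 genes, the one with the highest mean over all arrays was used, giving 22180 genes. Genes at or below the 30th percentile of the mean over all arrays (4.38 on the log2 scale) were left out, which removed 6654 and left 15526.

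Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, Bcl2l1-deleted minus control), two-sided, with Benjamini-Hochberg adjustment over all tested genes. Every adjusted p of a single gene is from this fit unless another setting is named beside it. A relative change is the fitted log2 change minus that of the median tested gene. The SE and adjusted p printed beside a relative change are those of the fitted change, which was tested against no change. Named genes were Bcl2l1, the 10 largest increases and 10 largest decreases among genes past an adjusted p of 0.05 whose groups did not overlap, and up to 4 members with the smallest p of each list described. Predicted genes (symbols in Gm with a number or ending in Rik), microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were excluded from the largest changes.

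The 35 gene lists held 471 entries, of which 407 were tested. Pathway lists covered the Sonic hedgehog pathway, the BCL2 family without Bcl2l1, apoptosis execution, p53 targets, cell cycle, DNA damage repair, interferon response, inflammatory cytokines, antigen presentation, oxidative phosphorylation, mitochondrial dynamics, glycolysis, hypoxia, the unfolded protein and integrated stress response, autophagy and lysosome, heat shock, immediate early genes and the genes flanking Bcl2l1. Cell type lists covered granule neuron progenitors and differentiation, stem-like cells, microglia, phagocytic microglia, border macrophages, infiltrating leukocytes, astrocytes, oligodendrocytes and their precursors, Purkinje cells, inhibitory interneurons, endothelial, mural and fibroblast cells, choroid plexus and ependyma, and erythroid cells. Members not measured by a probe set of their own were not analysed here, and the member counts given are of tested genes. Lists with at least 4 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated. The fry test, which asks whether a list moves one way without comparing it with other genes, was an alternative. Single values per array were compared by exact permutation over the 70 regroupings, whose smallest two-sided p is 0.0286.

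The fit was tested on simulated data in the layout of Bcl2l1-deleted against control arrays with 15526 genes. It recovered 95.0% of 100 genes changed by 2 log2 units and 56.0% of 100 genes changed by 1, with 9 false calls, and 3 of 3 shifted lists with 0 false ones. The simulated noise was independent between genes and the lists were random. How the list test behaves with correlated genes or an outlying array was therefore not tested by it.

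Alternatives fixed before the data were examined were other dim filters, an intensity trend, a robust prior, a plain linear model, quantile normalization, median centring, array weights, a replicate block, the Xist level as a covariate, other choices of probe set, a fold minimum, other list tests, and leaving out each array. Centring on the tested genes, the receptor median as a covariate, and further settings without control replicate 2 were added after seeing the data.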

Results

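Gene expression was measured in medulloblastomas, tumours of the cerebellum, taken at postnatal day 15 from mice of 2 genotypes. All the mice carried Math1-Cre and SmoM2, so that Cre driven from the Math1 (Atoh1) promoter switches on an active form of the Sonic hedgehog receptor component Smoothened in granule neuron precursors. In 4 of the tumours Cre also deleted Bcl2l1, the gene of the anti-apoptotic protein BCL-xL, through floxed alleles, and 4 control tumours kept the gene. Each tumour came from a separate animal and was hybridised to 1 Affymetrix whole-transcript array. The values are log2 RMA expression values, with medians between 4.77 and 5.17 over all probe sets of an array, and with 4 arrays per group the number of animals limits the precision. Xist was high on 2 of the 4 Bcl2l1-deleted arrays and on 3 of the 4 control arrays, so both sexes were present in both groups.

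Control replicate 2 stood apart from the other 7 arrays. Its correlations with them lay between 0.920 and 0.948, while all other pairs reached at least 0.966. The interquartile range of the named genes was 2.40 on this array, against 3.29 to 3.50 on the other controls and 3.59 to 3.66 on the Bcl2l1-deleted arrays. The chemosensory receptor genes (Olfr and Vmn), which report mostly background in brain, had a median of 3.60 there, 2.94 to 3.09 on the other controls and 2.79 to 2.92 on the Bcl2l1-deleted arrays. Background was thus lower and the signal range wider on every Bcl2l1-deleted array than on every control array (exact permutation test, two-sided, p = 0.0286 for each measure, and 0.0286 without control replicate 2, the smallest value these group sizes allow with or without that array).

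**Figure D1:**
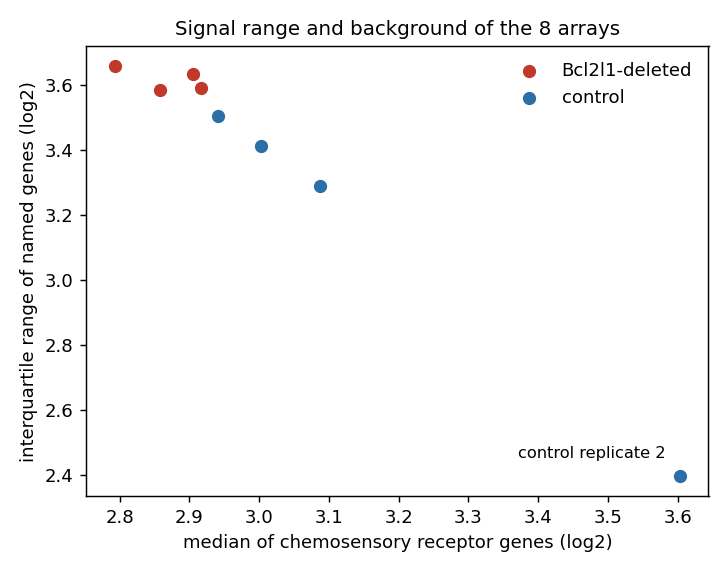
Median of the chemosensory receptor genes (horizontal axis, log2) against the interquartile range of all named genes (vertical axis, log2), 1 point per array, for the 4 Bcl2l1-deleted and 4 control tumours. Control replicate 2 lies at 3.60 and 2.40, away from the others, and the Bcl2l1-deleted arrays have the lowest medians and the widest ranges.

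The comparison of the genotypes asks how the tumour transcriptome differs when Bcl2l1 is deleted. Bcl2l1 itself fell by 1.36 on the log2 scale (SE 0.16, 2.56-fold lower, adjusted p = 0.00509). Its mean was 5.48 ± 0.15 (SD, n = 4) in the Bcl2l1-deleted tumours and 6.84 ± 0.19 (SD, n = 4) in the controls, without overlap (exact permutation test, two-sided, p = 0.0286). Only 1 probe set (17392991) names the gene, and whether it lies in the deleted part was not analysed here, so the remaining signal has no direct reading as intact transcript. None of the 18 tested genes that neighbour Bcl2l1 passed, and Commd7 had the largest decrease among the 4 with the smallest p (relative log2 change -0.87, adjusted p = 0.0561). Without control replicate 2, 2 neighbours were higher and 1, Commd7, lower (adjusted p = 0.0136), and 2 were higher without control replicate 1. The call of Bcl2l1 held in all 22 alternatives that gave it a value.

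Among 15526 genes tested, 1013 passed an adjusted p of 0.05, and 975 of these had groups that did not overlap. Over all tested genes, 3637 (23.4%) did not overlap, where chance gives 2.86%. At an unadjusted p under 0.05 (limma), 4730 of the 15526 genes passed. Several members of any list can therefore pass when adjusted over the list alone, and such counts are not particular to a list. The median tested gene was 0.17 higher in the Bcl2l1-deleted tumours on the log2 scale, so changes are given below relative to that median unless called fitted. Of the 1013 genes, 765 were higher and 248 lower, but this split followed the scaling. Centring each array on its median gave 1337 higher and 171 lower, centring on the median of the genes tested gave 390 higher and 699 lower, and the receptor median as a covariate gave 273 higher and 404 lower, the last pair of settings being chosen after seeing the data. The number of genes also moved with every array: it was 20, 47, 453 and 223 without Bcl2l1-deleted replicates 1 to 4 in turn, and 1999, 2100, 461 and 157 without control replicates 1 to 4. With the Xist level as a covariate 203 genes passed.

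Ttr, which encodes the thyroxine carrier transthyretin, made in quantity by the choroid plexus, had the largest change of the named genes. Its mean was 6.07 ± 0.54 (SD, n = 4) in the Bcl2l1-deleted tumours and 11.20 ± 0.22 (SD, n = 4) in the controls, 35.2-fold lower (adjusted p = 7.3e-06), and its call held in every alternative run. The other large decreases included genes of cerebellar neurons and of myelin. Fat2, a protocadherin of granule neurons, changed by -2.85 ± 0.50 (relative log2 change ± SE), the calcium pump gene Atp2b3 by -2.78 ± 0.44, the myelin gene Mobp by -2.72 ± 0.47, the vesicular glutamate transporter gene Slc17a7 by -2.47 ± 0.42 and the cerebellin gene Cbln3 by -2.35 ± 0.44. The small RNA genes Scarna6 (-2.47 ± 0.33) and Rny1 (-2.30 ± 0.43) fell as well. LOC100861738 (-2.47 ± 0.59) and BC061237 (-2.44 ± 0.52) completed the 10 largest decreases, and both stood highest on control replicate 2, LOC100861738 at 9.87 (6.55 to 7.52 on the other controls) and BC061237 at 9.79 (7.06 to 7.26). Without that array they still passed, with fitted changes of -1.57 and -1.61 (adjusted p = 0.0109 and 0.00459). Both LOC100861738 and Rny1 lost their calls in several settings, among them centring on the genes tested for LOC100861738 (adjusted p = 0.0585) and the receptor median as a covariate for Rny1 (adjusted p = 0.0959).

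The 10 largest increases included genes known from macrophages. Lilrb4a, an inhibitory leukocyte receptor, rose by 2.22 ± 0.27 (relative log2 change ± SE), the scavenger receptor gene Colec12 by 1.83 ± 0.26, Ms4a7 by 1.83 ± 0.27 and Ms4a6d by 1.68 ± 0.33. Cybb, a subunit of the phagocyte NADPH oxidase, rose by 1.75 ± 0.32, Atp6v0d2, a subunit of the proton pump of lysosomes, by 1.84 ± 0.32, and Npl, which splits sialic acid, by 1.73 ± 0.27. Ahcy, the hydrolase of S-adenosylhomocysteine, rose by 2.14 ± 0.25, from a mean of 6.14 ± 0.47 (SD, n = 4) to 8.46 ± 0.32 (SD, n = 4), with an adjusted p of 0.00509. Cd4 rose by 1.81 ± 0.34 and the signalling ligand gene Bmp4 by 1.74 ± 0.29. Of these 20 largest changes, 5, 8, 18 and 14 stayed past the threshold without Bcl2l1-deleted replicates 1 to 4 in turn, and 20, 20, 18 and 12 without control replicates 1 to 4. The highest adjusted p among these was 0.134, without Bcl2l1-deleted replicate 2. Of all 69 named genes that passed besides Bcl2l1, 8, 12, 37 and 32 and then 65, 68, 41 and 26 stayed in the same order, and all 69 kept their direction.

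**Figure D2:**
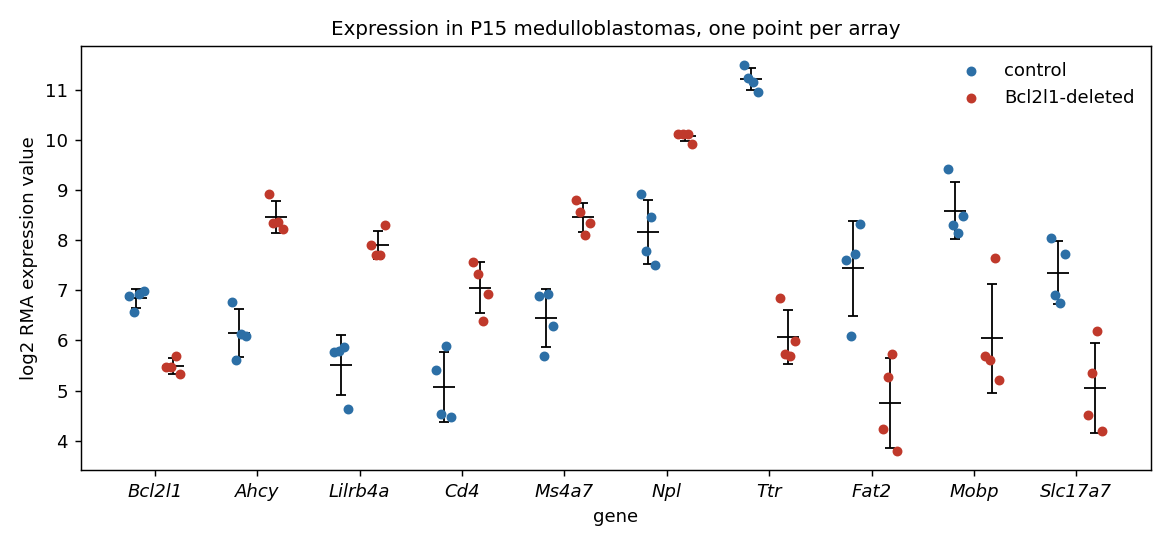
log2 RMA expression values (vertical axis) of Bcl2l1, 5 genes that rose and 4 that fell (horizontal axis), with 1 point per array, the mean as a horizontal bar and the SD as whiskers, for 4 control and 4 Bcl2l1-deleted tumours. The groups do not overlap for any of these genes, and Ttr drops from a mean of 11.20 to 6.07.

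Gene lists fixed before the data were examined were compared with all other tested genes. Of 34 lists with enough tested genes, 12 passed camera at an adjusted p of 0.05, 7 towards higher and 5 towards lower expression. No list passed when the correlation among genes was estimated from the arrays (camera, lowest adjusted p = 0.517, where 16 lists had an unadjusted p under 0.05 with the preset correlation and 13 passed fry), so each list's estimated value stands beside it below. Of the 12 lists, those of oligodendrocytes, Purkinje cells, inhibitory interneurons and DNA damage repair did not pass fry (adjusted p = 0.169, 0.285, 0.317 and 0.0685). In 3 of the 35 divisions of the 8 arrays into 4 and 4, the real one included, as many lists passed, with up to 13 in another division.

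Markers of differentiating granule neurons were lower as a group with camera's preset correlation, though not with an estimated one. Of 19 measured members, 8 fell, none rose and 11 did not pass, and 11 fell when adjusted over the list alone. Leaving out Bcl2l1-deleted replicates 1 to 4 in turn left 1, 1, 9 and 3 members lower, and control replicates 1 to 4 left 7, 10, 7 and 1. Cntn2, an adhesion molecule of migrating granule neurons, changed by -1.37 ± 0.15 (relative log2 change ± SE), the glutamate receptor gene Grm4 by -1.82 ± 0.29, and Slc17a7 and Fat2 by the values above. The list mean was -1.26 (camera adjusted p = 4.1e-11, adjusted p = 0.579 with an estimated correlation). Markers of myelinating oligodendrocytes had a mean of -1.02 (adjusted p = 8.9e-05, adjusted p = 0.650 with an estimated correlation), with Mobp and Mal (-1.76 ± 0.35) lower among 11 members, and 5 lower when adjusted over the list alone. Lower oligodendrocyte members numbered 0, 0, 4 and 0 without Bcl2l1-deleted replicates 1 to 4 in turn and 2, 4, 2 and 0 without control replicates 1 to 4, with 1 member higher without control replicate 1. Opalin (-1.32) and Ermn (-1.64) did not pass over all genes (adjusted p = 0.0574 and 0.0695). Oligodendrocyte precursor markers did not pass as a list (mean 0.30, camera adjusted p = 0.194, but called in 1 of 25 alternatives), although Gpr17 (1.14 ± 0.24) and Sox10 (0.59 ± 0.19) rose among 7 members, 2 when adjusted over the list alone. In the same order of arrays left out, 0, 0, 1 and 1 and then 2, 2, 1 and 1 precursor markers were higher. Lower interneuron markers numbered 0, 0, 2 and 0 and then 1, 1, 0 and 0. The Purkinje cell list was lower (mean -1.41, adjusted p = 0.00569, adjusted p = 0.650 with an estimated correlation), but none of its 6 members passed, also when adjusted over the list alone, and Calb1 had a standard error of 1.00 beside its -2.01. Its score was highest of all 8 arrays on Bcl2l1-deleted replicate 3 (3.01, against 1.58 to 2.62 on the controls), so the groups overlapped (exact permutation test, two-sided, p = 0.229). The mean was -2.18 without that array, where 1 member was lower, and -0.71 without Bcl2l1-deleted replicate 4. The Purkinje call was lost when arrays were centred on the genes tested (adjusted p = 0.0929), with the mean unchanged. In the inhibitory interneuron list (mean -0.79, adjusted p = 0.0200, adjusted p = 0.650 with an estimated correlation) the glycine transporter gene Slc6a5 fell by 1.77 relative to the median gene, 1 of 6 members on either adjustment. Its score was again highest on Bcl2l1-deleted replicate 3 (0.38, exact permutation p = 0.143 for the groups), and the mean was -1.20 without that array. That list was no longer called without Bcl2l1-deleted replicate 1 or 4 (adjusted p = 0.0534 and 0.0625), without control replicate 1 (0.0680), or centred on the genes tested (0.0929, with the mean unchanged).

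Choroid plexus and ependyma markers had a mean of -1.41 over 6 members (adjusted p = 8.9e-05, adjusted p = 0.517 with an estimated correlation). Ttr and the folate receptor gene Folr1 (-1.14 ± 0.19) fell, and 3 members fell when adjusted over the list alone. Choroid plexus members lower over all genes numbered 1, 1, 2 and 1 without Bcl2l1-deleted replicates 1 to 4 in turn and 2, 2, 2 and 2 without control replicates 1 to 4. Kl (-0.75, adjusted p = 0.111) and Clic6 (-0.84, adjusted p = 0.192) did not pass over all genes.

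Microglia markers were higher as a group with camera's preset correlation, though not with an estimated one. Of 19 measured members, 9 rose, none fell and 10 did not pass, and 18 rose when adjusted over the list alone. Leaving out Bcl2l1-deleted replicates 1 to 4 in turn left 0, 0, 2 and 3 members higher, and control replicates 1 to 4 left 15, 10, 6 and 2. Aif1, the cytoskeletal protein IBA1, rose by 1.12 ± 0.21 (relative log2 change ± SE), the protease gene Ctss by 1.08 ± 0.20, Ly86 by 1.19 ± 0.32 and the complement gene C1qa by 0.77 ± 0.19. The list mean was 0.72 (camera adjusted p = 7.9e-06, adjusted p = 0.650 with an estimated correlation). With each array centred on the genes tested 5 members rose, and with the receptor median as a covariate 2 rose. Border macrophage markers had a mean of 0.53 (adjusted p = 0.0338, adjusted p = 0.650 with an estimated correlation), with Ms4a7 and the mannose receptor gene Mrc1 (1.24 ± 0.22) higher among 8 members and 3 when adjusted over the list alone. Their call was lost without Bcl2l1-deleted replicate 3 (adjusted p = 0.0901) and without control replicate 3 or 4 (0.111 and 0.0719). The phagocytic microglia list did not pass (mean 0.34, camera adjusted p = 0.0621), although it did in 16 of 25 alternatives (adjusted p = 0.0332 with fry), with Igf1 (1.20 ± 0.20) and Gpnmb (0.92 ± 0.27) higher among 14 members and 6 higher when adjusted over the list alone. With Bcl2l1-deleted replicates 1 to 4 and then control replicates 1 to 4 left out in turn, 0, 1, 2 and 2 and then 3, 2, 2 and 2 border macrophage markers were higher. Higher phagocytic microglia markers numbered 0, 1, 1 and 1 and then 6, 4, 1 and 1. Of 14 measured infiltrating leukocyte markers 10 lay below the dim filter, and of the 4 tested only Cd4 rose, on either adjustment, while Cd8a, Cd79a and Nkg7 stood at -0.17, -0.07 and -0.25 (adjusted p = 0.981, 0.710 and 0.821). The leukocyte list did not pass (adjusted p = 0.740, mean 0.33, median -0.12). The call of Cd4 was lost without Bcl2l1-deleted replicate 1 or 2 (adjusted p = 0.0729 and 0.0649) or control replicate 4 (0.0536).

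Inflammatory cytokine genes had a mean of 0.54 (camera adjusted p = 0.00615, adjusted p = 0.517 with an estimated correlation). Of 13 members 6 rose and none fell, and 8 rose when adjusted over the list alone. Higher cytokine genes numbered 1, 1, 3 and 3 without Bcl2l1-deleted replicates 1 to 4 in turn and 7, 7, 5 and 2 without control replicates 1 to 4, with 1 lower without control replicate 1. Ccl3 rose by 1.62 ± 0.35 (relative log2 change ± SE), Il1a by 1.28 ± 0.29, the macrophage growth factor gene Csf1 by 1.13 ± 0.26 and Tnf by 0.90 ± 0.13. The call of Tnf held in every alternative that gave it a value. With the receptor median as a covariate 3 members rose. The interferon response list did not pass (mean 0.30, adjusted p = 0.0722, but called in 8 of 25 alternatives), with Ifih1 (0.79 ± 0.22), Rtp4 (0.60 ± 0.19) and Cxcl10 (1.02 ± 0.31) higher among 16 members and 3 when adjusted over the list alone. Cxcl10 lost its call without control replicate 2 (adjusted p = 0.0608). Antigen presentation genes did not pass as a list (mean 0.16, adjusted p = 0.189, but called in 4 of 25 alternatives), with the class I gene H2-K1 (0.66 ± 0.19) higher among 10 members and 2 when adjusted over the list alone. In the order given for the cytokines, 0, 0, 0 and 0 and then 2, 4, 1 and 0 interferon genes were higher. Higher antigen presentation genes numbered 0, 0, 0 and 0 and then 1, 2, 0 and 0. With the receptor median as a covariate 0 interferon and 0 antigen presentation genes were higher, and with arrays centred on the genes tested 1 and 1.

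Fibroblast markers had a mean of 0.75 (camera adjusted p = 0.00221, adjusted p = 0.650 with an estimated correlation), with 4 of 8 members higher and 5 when adjusted over the list alone. The matrix genes Ogn (1.62 ± 0.24), Dcn (1.47 ± 0.25) and Col1a2 (0.53 ± 0.17) and the transporter gene Slc6a13 (1.05 ± 0.28) rose. Endothelial markers had a mean of 0.44 (adjusted p = 0.00221, adjusted p = 0.650 with an estimated correlation), with 4 of 11 members higher and 7 when adjusted over the list alone, among them the junction genes Cldn5 (0.91 ± 0.22), Cdh5 (0.73 ± 0.14) and Esam (0.86 ± 0.20) and the receptor gene Tek (0.67 ± 0.20). Mural cell markers did not pass as a list (mean 0.43, adjusted p = 0.0794, but called in 7 of 25 alternatives), with Rgs5 (0.89 ± 0.28), Vtn (0.89 ± 0.27) and Acta2 (0.53 ± 0.16) higher among 8 members and 4 when adjusted over the list alone. Astrocyte markers did not pass either (mean 0.41, adjusted p = 0.0534, but called in 13 of 25 alternatives), with the water channel gene Aqp4 (0.80 ± 0.24), Aldh1l1 (0.72 ± 0.20) and S100b (0.99 ± 0.28) higher among 12 members and 5 when adjusted over the list alone. Higher fibroblast markers numbered 1, 1, 2 and 3 without Bcl2l1-deleted replicates 1 to 4 in turn and 4, 5, 2 and 2 without control replicates 1 to 4. In that order, 0, 0, 2 and 2 and then 5, 4, 2 and 1 endothelial markers were higher. Higher mural markers numbered 0, 0, 0 and 1 and then 3, 4, 0 and 0. Higher astrocyte markers numbered 0, 0, 0 and 0 and then 7, 3, 0 and 0. With the receptor median as a covariate 2 fibroblast, 2 endothelial, 1 mural and 0 astrocyte members rose (limma). The astrocyte mean was then 0.18.

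Cell cycle genes had a small positive mean of 0.24 over 29 members (camera adjusted p = 0.000717, adjusted p = 0.702 with an estimated correlation). The mitotic genes Aurkb (0.45 ± 0.14), Bub1b (0.45 ± 0.16) and Cdc20 (0.39 ± 0.15) and the cyclin gene Ccne1 (0.53 ± 0.17) rose, and 10 members rose when adjusted over the list alone. With arrays centred on the genes tested none of the 29 passed in limma. In the fit of the deposited values, higher cell cycle genes numbered 0, 0, 0 and 0 without Bcl2l1-deleted replicates 1 to 4 in turn and 4, 7, 0 and 0 without control replicates 1 to 4. DNA damage repair genes had a mean of 0.32 over 14 members (adjusted p = 0.0121, adjusted p = 0.702 with an estimated correlation), with the checkpoint kinase gene Chek2 (0.75 ± 0.23) and Xrcc6 (0.39 ± 0.15) higher and 5 when adjusted over the list alone. In the same order 0, 0, 0 and 0 and then 2, 2, 0 and 0 repair genes were higher. That list was not called with the receptor median as a covariate (adjusted p = 0.101) or with a dim filter at the 50th percentile (0.0539).

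Genes of the BCL2 family other than Bcl2l1 did not pass as a list (mean -0.15, camera adjusted p = 0.796). Of 14 members only Hrk, which encodes a BH3-only protein that binds BCL-xL, changed, by -1.52 ± 0.33 (relative log2 change ± SE), also when adjusted over the list alone (1 lower). Its call was lost when any single array except control replicate 2 was left out. The adjusted p was 0.134, 0.101, 0.0876 and 0.0635 without Bcl2l1-deleted replicates 1 to 4 in turn, and 0.0532, 0.0741 and 0.0768 without control replicates 1, 3 and 4. With arrays centred on their median it was 0.0566. Mcl1, another anti-apoptotic member, stood at 0.28 ± 0.16 (adjusted p = 0.0926) and Bcl2l11 at 0.27 ± 0.22 (adjusted p = 0.198). Apoptosis execution genes did not pass (mean 0.16, adjusted p = 0.204, but called in 2 of 25 alternatives), with none of 13 past the threshold on either adjustment and Casp8 at 1.02 ± 0.38 (adjusted p = 0.0797). Without control replicate 2, 2 of them were higher, Casp8 (adjusted p = 0.0333) and Birc3 (adjusted p = 0.0291). Targets of p53 did not pass as a list (mean 0.15, adjusted p = 0.152), although they did in 2 of 25 alternatives. Perp (0.72 ± 0.21), the death receptor gene Tnfrsf10b (0.61 ± 0.20) and Ccng1 (0.50 ± 0.18) rose among 18 members, 3 when adjusted over the list alone. With the receptor median as a covariate none of the 18 passed in limma. Without the covariate, higher p53 targets numbered 0, 0, 0 and 0 without Bcl2l1-deleted replicates 1 to 4 in turn and 3, 3, 0 and 0 without control replicates 1 to 4.

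Sonic hedgehog pathway genes did not pass (mean -0.08, camera adjusted p = 0.740), and none of 11 members did on either adjustment. Among them Smo stood at -0.40 ± 0.16, Atoh1 at 0.29 ± 0.17, Mycn at 0.07 ± 0.14 and Ccnd1 at 0.03 ± 0.14 (relative log2 change ± SE). Their fitted changes, to which the p-values belong, were -0.22, 0.46, 0.24 and 0.20 (limma adjusted p = 0.350, 0.108, 0.252 and 0.343). In the granule neuron progenitor list (mean -0.30, adjusted p = 0.189, but called in 4 of 25 alternatives) Meis2 fell by 1.72 relative to the median gene, 1 of 10 members on either adjustment. The stem-like list (mean 0.19, adjusted p = 0.281, but called in 1 of 25 alternatives) held 1 rise among 8 members, Hes5 (0.77 ± 0.16), and 2 when adjusted over the list alone, with Sox2 at 0.87 ± 0.28 (adjusted p = 0.0516). Lower progenitor genes numbered 0, 0, 1 and 0 without Bcl2l1-deleted replicates 1 to 4 in turn and 1, 2, 1 and 1 without control replicates 1 to 4. Higher stem-like genes numbered 0, 0, 1 and 1 and then 2, 2, 1 and 0 in that order.

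The remaining lists did not pass camera. The unfolded protein and integrated stress response list (mean 0.18, adjusted p = 0.152) was called in 3 of 25 alternatives. In it Atf3 rose by 0.75 ± 0.15 (relative log2 change ± SE), 1 of 13 members on either adjustment. The call of Atf3 was lost with arrays centred on the genes tested (adjusted p = 0.0693) and without Bcl2l1-deleted replicate 1 or 2 (0.0649 and 0.0618). No member passed over all genes in the lists of autophagy and lysosome (12 members, mean 0.13, adjusted p = 0.234, 2 higher when adjusted over the list alone), heat shock (8 members, mean 0.03, median -0.07, adjusted p = 0.724, 3 higher over the list alone), oxidative phosphorylation (18 members, mean 0.01, adjusted p = 0.554), mitochondrial dynamics (11 members, mean 0.04, median -0.02, adjusted p = 0.554), immediate early genes (11 members, mean -0.13, adjusted p = 0.627), hypoxia (9 members, mean -0.01, median 0.08, adjusted p = 0.938) and glycolysis (11 members, mean -0.05, adjusted p = 0.938). Single members of these lists were higher when an array was left out: autophagy 2, oxidative phosphorylation 1, mitochondrial dynamics 1 and immediate early genes 1 without control replicate 1, autophagy, heat shock, immediate early genes and glycolysis 1 each without control replicate 2, and hypoxia 1 without control replicate 3. As lists, heat shock was called in 2 of 25 alternatives and autophagy and lysosome in 1. The genes flanking Bcl2l1 had a mean of -0.04 (adjusted p = 0.892), with 3 higher and 1 lower when adjusted over the list alone. For hypoxia, glycolysis and the flanking genes camera gave the direction as higher although the mean lay below 0. The erythroid list had 1 tested member, Slc4a1, at -0.02 (adjusted p = 0.594), and was not tested as a list.

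**Figure D3:**
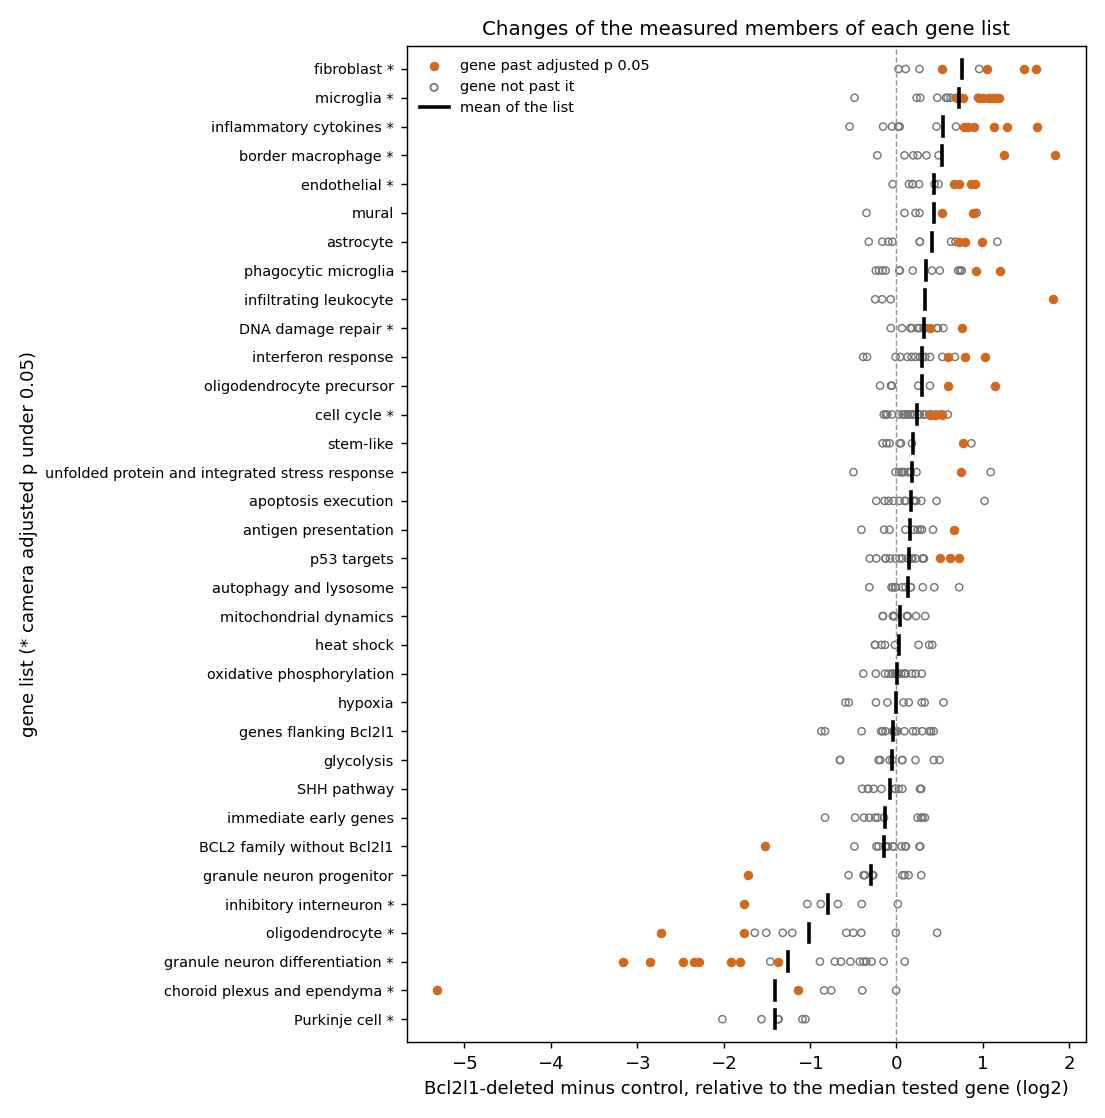
Change of each tested member of 34 gene lists (vertical axis) in Bcl2l1-deleted minus control tumours, relative to the median tested gene (horizontal axis, log2), with filled points for genes past an adjusted p of 0.05, open points for the others and a bar at the list mean. The granule neuron differentiation list lies at a mean of -1.26 and the microglia list at 0.72, and lists marked with an asterisk passed camera with its preset correlation, none of which did with an estimated one.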

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

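The tests of control replicate 2, of tissue composition, of Ttr and of Ahcy were chosen after the values they measure had been seen, while the counts over other divisions of the arrays were fixed before.

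A sample far from the other 3 of its group was sought in 150 named genes, 34 list scores and 4 array measures, 376 groups in all. The gap to the nearest sample, divided by the range of the group, exceeded Dixon's limit for 4 values in 24 groups, where chance gives about 1 in 20 (5%). Control replicate 2 was the distant sample for 10 genes: Ms4a6d (0.935), BC061237 (0.929), Bcl2l11 (0.937), H2-K1 (0.848), Tfam (0.843), Atf3 (0.851), Sox2 (0.922), Pdgfrb (0.858), Rgs5 (0.896) and Clic6 (0.894). It was also distant in the median of the tested genes (0.853, at 6.26 against 6.73 to 6.81) and in the mean correlation with its group (0.918, at 0.945 against 0.969 to 0.972). Control replicate 4 was distant for Lilrb4a (0.933, at 4.63 against 5.78 to 5.86) and control replicate 1 for Mal (0.864) and the fibroblast score (0.839). Bcl2l1-deleted replicate 4 was distant for Npl (0.920), Vtn (0.918) and the border macrophage score (0.854). Bcl2l1-deleted replicate 3 was distant for Ccnd1 (0.864), Tnf (0.839), the apoptosis execution score (0.858) and the stem-like score (0.859). Bcl2l1-deleted replicate 2 was distant for Junb (0.834), and replicate 1 for the oxidative phosphorylation score (0.8293).

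Control replicate 2 had a compressed signal. The slope of its values on the mean of the other 3 controls was 0.805, and the lowest slope of any other array on its own group was 0.987. Cells of another type mixed into the sample would not by themselves raise the chemosensory receptor genes, whose median lay 0.52 above the highest other control. That gap was larger than the SD of 0.0730 among the other controls. These genes cannot show whether such cells were present as well, so that stays open. A reduced range of the array, from RNA quality or hybridisation, is consistent with both values and stays open, since neither was measured here. Apart from mixed-in cells, no biological explanation was tested for this single array.

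With camera's preset correlation, though not with an estimated one (adjusted p = 0.579, 0.650 and 0.650), granule neuron and oligodendrocyte markers were lower and microglia markers higher in the Bcl2l1-deleted tumours, which also had lower array background, and the oligodendrocyte list did not pass fry (adjusted p = 0.169). With the receptor median as a covariate the microglia list kept 0.719 of its shift and stayed past the threshold with camera's preset correlation (adjusted p = 2.4e-05), although its higher members went from 9 to 2. The granule neuron list stayed as well. However, the receptor median itself separates the groups, and within them control replicate 2 lies far from the rest. This fit therefore cannot tell background from genotype, and background stays open as a source. For a lower share of tumour cells, the microglia score minus the oligodendrocyte score was examined, and it was higher by 1.74 (exact permutation p = 0.0286). Both lists were picked after their opposite shifts had been seen, so this difference was set by the choice. It shows only that the lists did not rise alike, and a changed share of tumour cells stays open. Less surrounding cerebellum in the Bcl2l1-deleted samples is left undecided, since the Purkinje and interneuron scores overlapped between the groups (exact permutation p = 0.229 and 0.143) and were highest of all on Bcl2l1-deleted replicate 3, and an effect of the Bcl2l1 deletion stays open as well. Less choroid plexus may contribute to the fall of Ttr, as 7 other choroid genes above the dim filter changed by -0.71 on average against genes of the same level (exact permutation p = 0.0286; -0.87 over 11 genes against the median of the genes tested, 4 of them below the filter). This is far less than the -5.31 of Ttr. However, the control means of those 7 genes ran from 5.17 (Calml4) to 7.81 (Otx2), against 11.20 for Ttr. A fall as large as that of Ttr would take even Otx2 to background, as the receptor median on the Bcl2l1-deleted arrays was 2.79 to 2.92. Smaller falls could still be seen. The brightest of these genes, Otx2, Kl and Clic6 (control means 7.81, 6.67 and 6.25), had room to fall further than their fitted changes of -0.22, -0.58 and -0.66. How much of their signal comes from choroid plexus was not measured, so how far choroid plexus accounts for Ttr cannot be told.

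Ahcy rose on all 4 Bcl2l1-deleted arrays, and it lies on the chromosome of Bcl2l1 as the 36th tested gene to one side. Its values come from probe set 17330769, and whether that probe set lies at the Ahcy gene was not analysed here. The comparison with neighbouring genes bears on the rise only if it does. Over 22 alternatives, which include other choices of probe set, the fitted change ran from 1.24 to 2.52, against 2.32 in the main fit. The compressed control replicate 2 does not account for the rise, since without that array the fitted change was 2.14 (adjusted p = 0.00342). Donor DNA around the floxed allele could differ in sequence under the probes, but of the 100 nearest tested genes 5 passed against 1006 of 15394 elsewhere (Fisher's exact test, one-sided, p = 0.789). One gene may still carry such a difference, and without probe sequences this cannot be told apart from an effect of the deletion.

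The 8 arrays can be divided into 4 and 4 in 35 ways. For the 1013 genes past the threshold, 1 division, the real one, gave as many, and the highest of the others was 0 in limma. The same held for the 765 higher genes (1 division, highest other 0) and the 248 lower genes (1 division, highest other 0). A share of 1 in 35 is the smallest this design allows, and every other division mixes the groups. The real division also splits the arrays by background and signal range, so these counts cannot be credited to genotype alone. For the 12 lists chance is not excluded, as 3 divisions gave as many and the highest other gave 13.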

How the results depend on the processing

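Alternatives added after seeing the data were centring on the genes tested, the receptor median as a covariate, and estimated correlation, fry or a further array left out without control replicate 2. The fitted Bcl2l1 change kept its call in all 22 alternatives (-1.61 to -1.18, adjusted p from 0.000349 to 0.0367; -1.45 to -1.30 over single arrays left out). Counts are given as all genes, higher and lower, against 1013, 765 and 248. They were 548, 389 and 159 without a dim filter (22180 genes tested), 3494, 2442 and 1052 with array weights, 203, 150 and 53 with the Xist covariate and 43, 37 and 6 in a plain linear model, which borrows no variance between genes. With a filter at the 50th percentile 160 were lower, and with median centring 1337 were higher. Centring on the genes tested gave 390 higher and 699 lower, and the receptor covariate 273 and 404. Leaving out 1 array gave 20 to 2100 genes, 16 to 1612 higher and 4 to 710 lower, and 1001 of the 1013 genes were shared with the fit without control replicate 2. Leaving out control replicate 2 and another array gave 571 to 2669 genes, with 2064 for Bcl2l1-deleted replicate 3. Lists past the threshold numbered 20 without a dim filter, 0 with an estimated correlation, 0 with it and without control replicate 2, and 11 to 15 over single arrays left out. Of 69 named genes called besides Bcl2l1, Ttr, Tnf and Cntn2 kept their calls in all alternatives that gave them a value, and none of the 12 called lists did, each losing it with an estimated correlation. No named gene or list reversed while called. Same-numbered arrays correlated at 0.04, 0.02, -0.13 and 0.05 in their deviations from group means, so no pairing by number was seen. With so few arrays and an outlying control replicate 2, a pairing cannot be excluded. A replicate block gave 508, 358 and 150 genes. Beyond these constructions the cause was not tested. Near background, differences are compressed, which limits what can be seen for dim genes.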

Other observations

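The gene families described here were chosen after the calls were seen, and the tests use those same calls. Their p-values therefore reflect the choice and give no separate support. Fisher's exact tests (one-sided, adjusted over 13 families in both directions) take genes as units, which are not independent replicates. Families known from myeloid cells held more higher genes than the rest. Some of their called members, such as Ms4a7, Ms4a6d and Ctss, and Ccl3 and Cxcl10 among the chemokines, were already named above. Of 7 tested Ms4a genes 6 were higher (adjusted p = 8.2e-07), of 13 cathepsin genes 6 (adjusted p = 0.000116), of 11 Toll-like receptor genes 5 (adjusted p = 0.000448) and of 4 Fc gamma receptor genes 2 (adjusted p = 0.0322). Their medians relative to the median gene were 1.06, 0.59, 0.43 and 1.10. Without Bcl2l1-deleted replicate 1 these counts were 1, 0, 0 and 0, without replicate 2 they were 3, 0, 0 and 0, without replicate 3 they were 6, 3, 2 and 2, and without replicate 4 they were 5, 1, 0 and 2. Without control replicates 1 to 4 in turn they were 6, 10, 5 and 3, then 6, 8, 5 and 4, then 6, 4, 4 and 2, and then 5, 1, 0 and 1. With arrays centred on the genes tested 5, 4, 3 and 2 were higher, and with the receptor median as a covariate 6, 2, 2 and 2, and no family had a lower gene in either. Of 23 chemokine genes 6 were higher and 1 lower (adjusted p = 0.00256 for higher), with a median of -0.05 that turned to 0.28 with the covariate. Without the covariate, higher chemokine genes numbered 0, 2, 5 and 4 without Bcl2l1-deleted replicates 1 to 4 in turn and 6, 6, 4 and 3 without control replicates 1 to 4.

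Families that held more lower genes than the rest included neuronal channels and synaptic genes, although most of their members did not pass. Of 76 potassium channel genes 5 were lower and 2 higher (adjusted p = 0.0191 for lower), of 17 synaptotagmin genes 3 were lower (adjusted p = 0.00670), and of 12 GABA-A receptor genes 3 were lower and 2 higher (adjusted p = 0.00259 for lower). Short RNA genes stood out in the same direction: 13 of 62 small nucleolar RNA genes (adjusted p = 3.5e-10) and 17 of 172 microRNA genes (adjusted p = 3.0e-08) were lower. The chemosensory receptor genes moved with them, 11 of 151 being lower (adjusted p = 0.000162), which is the background measure that differs between the groups. Lower genes among the potassium channel, small nucleolar RNA, microRNA and chemosensory receptor genes numbered 0, 1, 0 and 0 without Bcl2l1-deleted replicate 1, then 0, 1, 1 and 0 without replicate 2, then 6, 8, 12 and 1 without replicate 3, and 1, 3, 5 and 1 without replicate 4. They numbered 5, 16, 32 and 25 without control replicate 1, then 14, 17, 30 and 24 without control replicate 2, then 3, 5, 11 and 4 without control replicate 3, and 1, 7, 4 and 2 without control replicate 4. Lower synaptotagmin genes numbered 0, 0, 2 and 0 without Bcl2l1-deleted replicates 1 to 4 in turn and 2, 4, 1 and 0 without control replicates 1 to 4. Lower GABA-A receptor genes numbered 0, 0, 2 and 0 and then 2, 3, 1 and 0 in that order, with higher ones numbering 0, 0, 0 and 0 and then 3, 2, 0 and 0. Centring on the genes tested gave 15 small nucleolar RNA and 26 microRNA genes lower, and with the receptor median as a covariate 8 small nucleolar RNA genes and 8 microRNA genes were lower, as were 11 potassium channel and 5 synaptotagmin genes. The counts of both channel families followed the scaling. With arrays centred on their median 3 potassium channel genes were lower and 3 higher, and with arrays centred on the genes tested 11 were lower and 1 higher. For the GABA-A receptor genes these settings gave 1 lower and 2 higher, and 3 lower and 1 higher, and the covariate gave 3 lower and 0 higher.

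Probe sets outside the single-symbol ones were fitted and adjusted together, apart from the main fit. Of these, 1362 with several symbols were bright enough to test and 0 passed in limma (496 at an unadjusted p under 0.05). Of 7411 without a symbol 1 passed, lower in the Bcl2l1-deleted tumours (1674 at an unadjusted p under 0.05). In the main fit 4730 of 15526 genes had an unadjusted p under 0.05 and 1013 passed. Because the fits and adjustments are separate, the 0 does not show that these probe sets were unchanged.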
